A study of Mus musculus with 4 samples.

How the data were processed

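RNA was extracted with Trizol from homogenized liver and libraries were made with a NEBNext Ultra kit for Illumina sequencing, per the labels' protocols. The kit is not stated to mark strand. Reads were processed with HISAT2 and featureCounts 1.5.0-p3 on mouse genome build GRCm38, per the submitters' processing notes. The HISAT2 version, the annotation release, the strand setting and the treatment of reads mapping to several places are not given in the sources used here. The deposited table holds raw counts per gene for 4 libraries, as whole numbers with column totals that differ between libraries, along with gene symbols, positions and lengths for 54532 genes. Of these gene IDs 54495 were found in the GENCODE annotation of the same build, 53585 of them with the same start, end and strand. Positions are printed as the table gives them.

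The 4 libraries were grouped by their titles as HFD (334, 335) and HFD with I3A (303, 305). The numbers are not shared between groups, so no pairing was fitted. The labels do not say in words that each library comes from its own animal, so the tests measure the spread between these libraries. Within a group the libraries differed by more than sampling noise (chi-square per degree of freedom 30.0 for HFD and 29.4 for I3A). Each was counted as 1 replicate, though such a difference does not show that the libraries come from separate animals. Pairs across the groups had chi-squares per degree of freedom from 44.2 to 90.1. By tested genes more than 2-fold apart, however, HFD 334 and I3A 303 were closer (750) than the HFD pair (1096) or the I3A pair (921). No label gives a batch, cage or date.

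Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default minimum of 10 counts, libraries were scaled by TMM, and group was the single term of a quasi-likelihood fit, with 2-sided tests and Benjamini-Hochberg adjustment at 0.05. The fit took a biological coefficient of variation of 19.9% over all genes and 3.55 prior degrees of freedom. CPM are read counts scaled to a common library size by TMM, except for sums over marker lists and the comparison of S100a8 and S100a9 with Lcn2, which use library totals. Mean log2 CPM used a prior count of 2. With 2 against 2, an exact permutation test of 1 gene cannot go below p = 0.333, so single genes rest on the spread shared across genes. Counts of 0 allow up to 3 counts of a library, which is 0.2 CPM or less here; such limits cover counting error only.

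Before the data were examined, 65 gene lists, the tests, the alternatives and the rule for naming genes were fixed. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, for lists with 3 or more tested genes, with adjustment over the 63 such lists. The correlation estimated per list and the fry test were alternatives; with 4 libraries and 2 groups such a correlation rests on 2 residual degrees of freedom. The named genes were to be the 10 largest rises and 10 largest falls past the threshold with a mean of at least 2 CPM, both I3A libraries on the same side of both HFD libraries, and no predicted or pseudogene symbols. As no gene passed, each direction was filled to 10 by the smallest unadjusted p. Examples of a list come from its 4 genes with the smallest unadjusted p; 1 gene that this would name is not reported here. A further 16 genes were to be given with values in any case.

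Alternatives were RLE, upper-quartile and library size scaling, no filter or at least 10 counts in every library, each library left out, DESeq2 1.42.0, limma-voom, protein-coding genes alone, an adjusted p under 0.1 and a 2-fold minimum. Added after the data were seen were a robust quasi-likelihood fit, the use of the fit without HFD 335 as a second reading of each list, and list medians between HFD 334 and I3A 303. The edgeR, DESeq2 and camera tests were tried on simulated data with the 13403 genes, means and spreads of these libraries and 200 changed genes. edgeR recovered 46.0%, 89.5% and 97.0% of genes changed 2-, 4- and 8-fold with 14, 17 and 27 false calls, and DESeq2 recovered 55.0%, 91.5% and 95.5% with 21, 32 and 36. A list shifted 1.2-fold was called by camera in 20 of 20 simulated runs, with 13 false list calls over all runs. Simulated genes varied independently of one another, and their spreads were edgeR's estimates, which are pulled together across genes. edgeR without the filter was also run on these simulated data and recovered 46.0%, 89.5% and 97.0%, with 14, 17 and 29 false calls. The simulation held only genes that had passed the filter, so it cannot show what low counts do to that setting. The remaining alternatives were not run on simulated data.

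Genes whose exons overlap another gene were looked up for the 258 genes in the tables of named genes. For 21 of them an overlapping gene held more than 10% of their counts.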

Results

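Messenger RNA of liver from C57BL/6 mice, a common inbred strain, was sequenced and counted per gene. Livers fell into 2 groups of 2. One group is labelled HFD, letters that in mouse liver studies usually stand for a high-fat diet. The other, called I3A below, received HFD together with I3A, a treatment the labels give only by this abbreviation. The series title poses the question of whether I3A acts on the respiration of liver mitochondria in a fatty liver model. No liver without HFD was analysed here, so values are set against HFD alone. The libraries held 15005668 counts (HFD 334), 15942728 (HFD 335), 15649281 (I3A 303) and 18255623 (I3A 305), and 1 count was worth between 0.0548 and 0.0666 CPM. Albumin took 4.95% to 5.72% of the counts and the mitochondrial genome 5.08% to 5.65%.

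Library HFD 335 held transcripts of tissues outside the liver. Genes of skeletal muscle summed to 1027 CPM there and to between 0.876 and 1.09 CPM in the other 3 libraries. Acta1, the actin of skeletal muscle, had 6221 counts and Ckm, the muscle creatine kinase, 1408 counts in HFD 335 and 0 counts in each other library, where 0 allows up to 0.2 CPM. Exocrine pancreas genes summed to 229 CPM against 12.1 to 25.5 CPM elsewhere, and smooth muscle and mesothelium genes to 118 CPM against 6.41 to 7.73 CPM. Each list that passed its test was therefore also tested without this library.

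**Figure D1:**
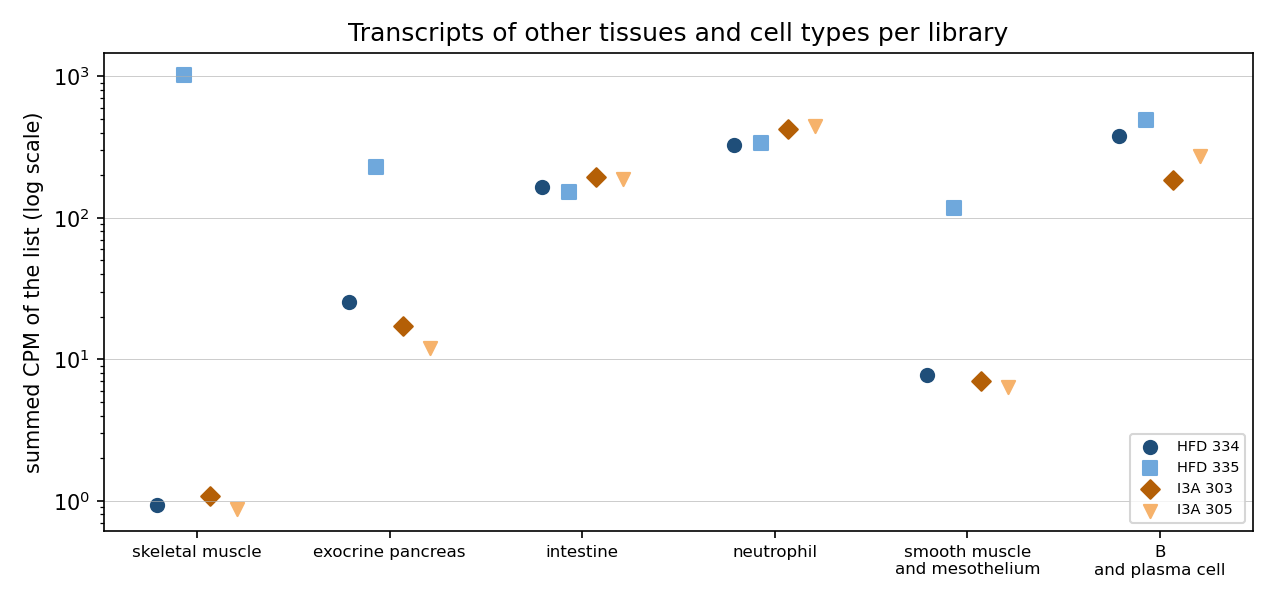
Summed CPM (log scale) of 6 lists of marker genes in each of the 4 libraries, 1 point per library. HFD 335 stands at 1027 CPM for skeletal muscle and 229 CPM for exocrine pancreas, above the other 3 libraries.

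Among the 20 genes named under the fixed rule, the largest difference between the groups was that of Saa2 (chromosome 7, 46751790 to 46754313, plus strand). Saa2 encodes serum amyloid A, a plasma protein released by hepatocytes in the acute phase. It measured 19.0 ± 9.54 CPM in HFD and 3109 ± 1822 CPM in I3A livers (SD, n = 2), a 163-fold higher level (log2 fold change 7.35, with 6.58 without I3A 305 and 7.99 without HFD 335). Fgl1, a fibrinogen-like protein secreted by hepatocytes, stood 4.10-fold higher (352 ± 72.9 CPM in HFD and 1445 ± 365 CPM in I3A livers). Slco1a4, an organic anion and bile acid uptake transporter, was 3.41-fold higher and Cyp8b1, the sterol hydroxylase that directs synthesis towards cholic acid, 1.95-fold higher (511 ± 20.1 CPM in HFD and 996 ± 2.19 CPM in I3A livers). Lower in I3A livers were the small chaperone Hspb1 (chromosome 5, 135887919 to 135889563, plus strand; 4.11-fold, 89.4 ± 16.1 CPM in HFD and 21.7 ± 3.23 CPM in I3A livers) and Nrep (29.1 ± 2.29 CPM in HFD and 7.27 ± 0.814 CPM in I3A livers). Lifr, the receptor of leukemia inhibitory factor, was 2.16-fold lower, and Serpina7, the thyroxine-binding globulin, 3.77-fold lower.

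The 20 genes were taken under a fixed rule, 10 per direction by the smallest unadjusted p. Only genes with a mean of at least 2 CPM, groups that did not overlap and no predicted or pseudogene symbol could be taken. The other 6 higher genes were Dhtkd1 of lysine breakdown (log2 fold change 0.95 ± 0.10, SE), Hoga1 of hydroxyproline breakdown (0.83 ± 0.10), Hnrnpa1 (0.76 ± 0.090), Camk1d (1.16 ± 0.14), Cyp2c40 (1.81 ± 0.20) and Cyp4a32 (0.94 ± 0.11). The other 6 lower genes were Rarres1 (-0.92 ± 0.090), the metalloreductase Steap4 (-1.16 ± 0.11), Saa4 (-0.95 ± 0.093), Rhobtb1 (-0.96 ± 0.10), the fatty acid elongase Elovl3 (-0.83 ± 0.092) and Synj2 (-1.87 ± 0.21). Saa2, Saa4, Cyp2c40 and Cyp4a32 have close relatives in the genome that share sequence, and how reads mapping to several copies were counted is not given in the sources used here, so their values are uncertain to that extent. Exons of Synj2 overlap those of Serac1 on the opposite strand.

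None of the 13403 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, where the smallest adjusted p was 0.141. All of the 20 genes above had edgeR adjusted p between 0.141 and 0.145. That both I3A livers lay on the same side of both HFD livers was a condition for naming them. At an unadjusted p under 0.05 stood 1729 genes, 892 higher and 837 lower, where chance alone would give 670. Among the fits with single libraries left out, that number was smallest without I3A 305, where it lay close to what chance gives. The excess therefore leans on this library. DESeq2 called 325 genes (175 higher, 150 lower), the 20 among them with adjusted p from 8.05e-17 to 2.31e-05, while limma-voom called 0. The groups did not overlap in 45.5% of tested genes, against 33.3% by chance for 2 against 2. Leaving out HFD 335 gave 21 genes (8 higher, 13 lower), leaving out HFD 334 gave 343 (39 higher, 304 lower) and leaving out I3A 303 gave 43, whereas without I3A 305 there were 0. On simulated counts of this design the edgeR test recovered 46.0% of 200 genes changed 2-fold and 89.5% of those changed 4-fold. False calls were 14 of 106 and 17 of 196. Simulated genes varied independently, with spreads that edgeR had already pulled together across genes. These shares therefore need not hold for the real libraries, where Saa2 did not pass despite its far larger difference.

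**Figure D2:**
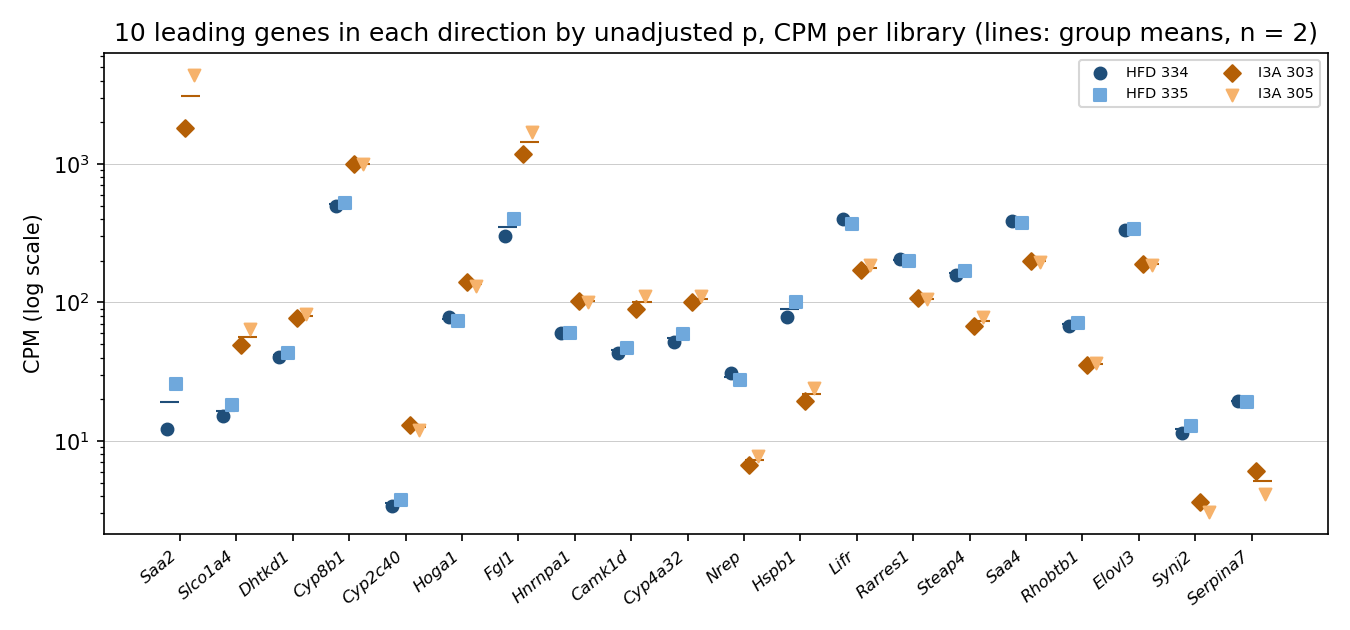
CPM (log scale) of the 20 genes named under the fixed rule, 1 point per library and short lines for the group means (n = 2 each). Saa2 moves from 19.0 to 3109 CPM. In each of the 20 genes the HFD and I3A points do not overlap, which the rule required.

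Of the 65 gene lists fixed for liver, 63 had 3 or more tested genes, and 25 passed camera's adjusted p of 0.05, with 10 higher and 15 lower in I3A livers. These calls use camera's preset correlation of 0.01 between genes. With the correlation estimated per list 0 of the 25 passed (adjusted p from 0.644 to 0.735), and fry's rotation test gave 0 (smallest adjusted p 0.407). Without HFD 335, 15 of the 25 still passed in the same direction. For single members below, rose and fell mean past an edgeR adjusted p of 0.05 adjusted over the list alone; adjusted over all tested genes the number is 0 in each list.

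**Figure D3:**
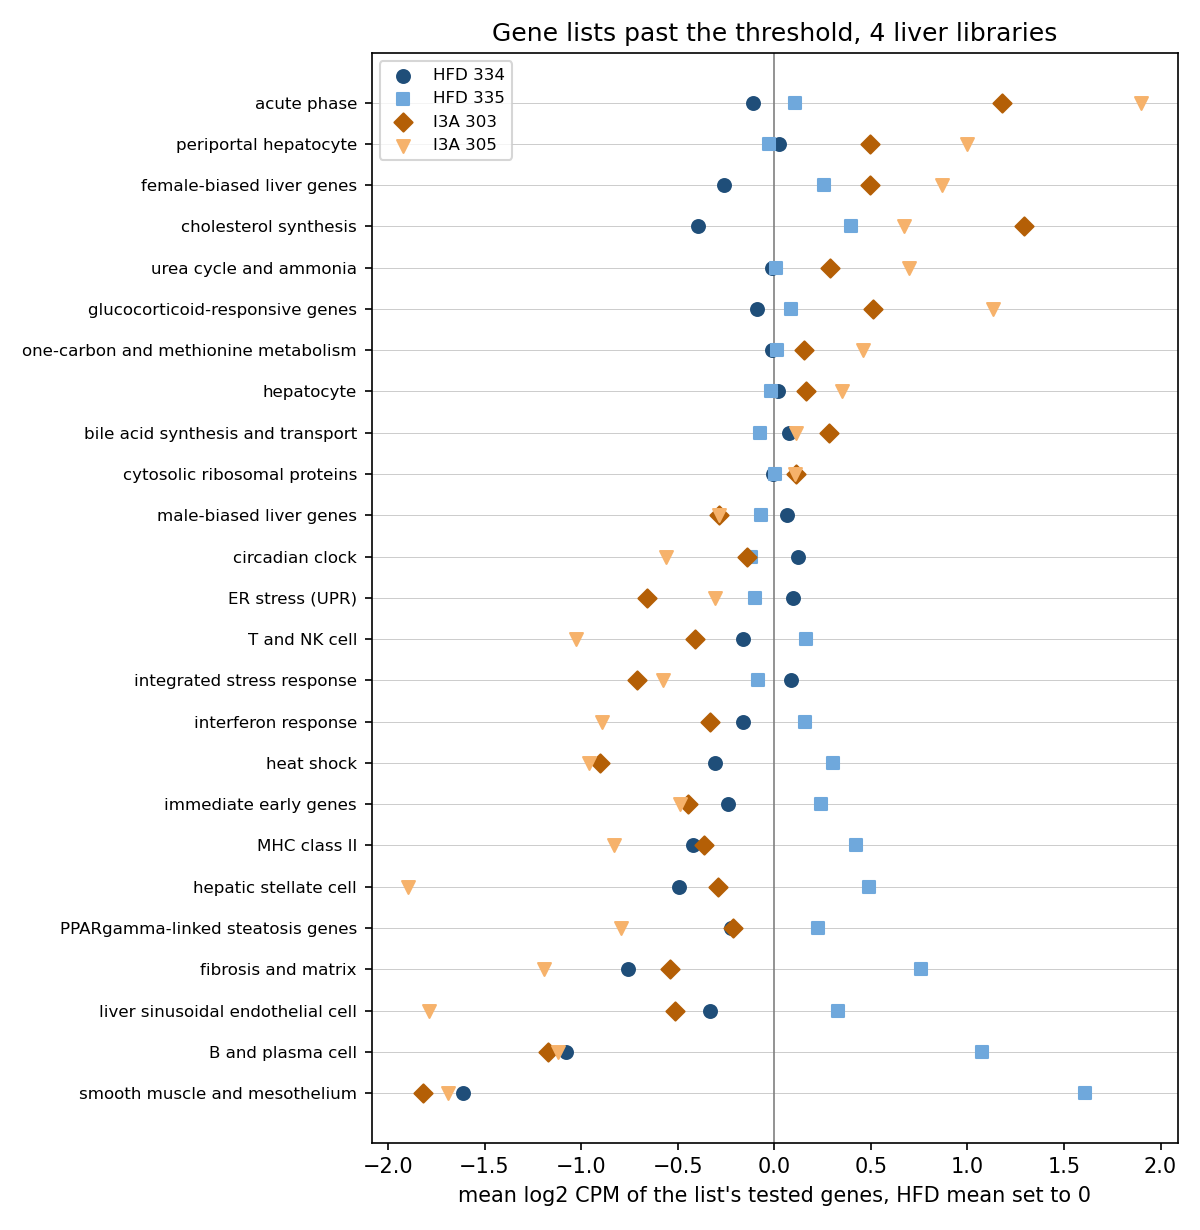
Mean log2 CPM of the tested genes in each of the 25 lists past the threshold, with the mean of the HFD libraries set to 0 and 1 point per library. The acute phase list lies furthest to the right and the lists of B and plasma cells and of smooth muscle spread between the 2 HFD libraries.

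Acute phase genes were higher in I3A livers: 15 of the 25 tested members rose and 3 fell (median log2 fold change 1.19; camera adjusted p = 6.71e-23; adjusted p = 0.644 with an estimated correlation). Saa1 rose 44.0-fold, from 94.8 ± 75.4 to 4171 ± 1507 CPM (SD, n = 2). Saa2 rose with it, whereas Steap4 and Saa4, the serum amyloid A made without an acute phase stimulus, fell. Saa1 and Saa2 are close relatives that share sequence. The value of Saa1 is therefore uncertain to the same extent, and the rises of Saa1 and Saa2 need not be independent. Genes known to respond to glucocorticoids were also higher as a list (median 0.32; camera adjusted p = 0.00315; adjusted p = 0.644 with an estimated correlation), with 5 of 14 members rising and 2 falling. Among them Lcn2, an iron-carrier binding protein that the acute phase list also holds, rose 33.3-fold from 7.62 ± 2.95 to 255 ± 207 CPM, the metallothionein Mt1 rose 10.8-fold and Igfbp1, a secreted binding protein of insulin-like growth factors, rose 2.60-fold. Zbtb16 in that list fell 2.40-fold. Without HFD 335, 13 acute phase members rose and 2 fell (median 1.17), and 3 glucocorticoid-responsive genes rose and 1 fell. The median of the latter list was 0.79 without HFD 334. The cytokine Tnf had 3 and 5 counts in HFD and 1 and 1 in I3A libraries, too few to test. Without I3A 305, 3 glucocorticoid-responsive genes rose and 3 fell, and the log2 fold changes were 5.03 (Saa1), 3.82 (Lcn2) and 2.17 (Mt1). Their highest values were 6.65 for Saa1 without HFD 335 and 5.73 for Lcn2 and 4.11 for Mt1 without I3A 303.

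Chaperones of the heat shock response were lower in I3A livers, with 11 of 14 members falling and 0 rising (median -0.74; camera adjusted p = 1.08e-17; adjusted p = 0.644 with an estimated correlation). Besides Hspb1, Hsph1 fell 1.84-fold, from 145 ± 2.02 to 78.4 ± 10.8 CPM, Hspa4l fell 1.74-fold and the co-chaperone Chordc1 1.60-fold. Genes of the unfolded protein response of the endoplasmic reticulum were lower as a list, with negative fold changes in all 23 tested members, of which 2 fell (median -0.39; camera adjusted p = 3.60e-10; adjusted p = 0.645 with an estimated correlation). These were Syvn1, a ubiquitin ligase of protein disposal from that compartment (log2 fold change -0.95 ± 0.14, SE), and Creld2 (-1.10 ± 0.16). The integrated stress response list was lower too (median -0.57; camera adjusted p = 6.28e-04; adjusted p = 0.644 with an estimated correlation), but 0 of its 16 members passed, and Atf4, its central transcription factor, measured -0.35 ± 0.11. Immediate early genes such as Jun (-0.93 ± 0.26) and Dusp6 (-1.30 ± 0.33) were lower as a list with 0 of 17 passing (camera adjusted p = 0.00828; adjusted p = 0.644 with an estimated correlation). Without HFD 335, 8 heat shock genes fell (median -0.53), 3 of the unfolded protein response and 6 of the integrated stress response (median -0.89), while the immediate early list no longer passed (median -0.031, adjusted p = 0.222), its median being -0.40 without I3A 305. The integrated stress response lost its call without HFD 334 (median -0.26, adjusted p = 0.299), and the median of the unfolded protein response was -0.19 without I3A 303. Without I3A 305, 7 heat shock genes and 14 of the unfolded protein response fell, and without HFD 334, 8 immediate early genes fell and 2 rose, with Dusp6 at -0.85 and Atf4 at -0.23.

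Lists of periportal hepatocytes, the urea cycle and one-carbon and methionine metabolism were higher in I3A livers. In the periportal hepatocyte list, which holds genes enriched around the portal vein, 10 of 15 members rose (median 1.01; camera adjusted p = 3.82e-13; adjusted p = 0.644 with an estimated correlation). Etnppl rose 2.19-fold and Hal, the histidine ammonia lyase, 2.37-fold. The urea cycle list was higher with 5 of 11 members rising (median 0.54; camera adjusted p = 9.07e-05; adjusted p = 0.644 with an estimated correlation); Cps1, its entry enzyme, rose 2.21-fold from 2654 ± 164 to 5872 ± 1739 CPM, Asl 2.43-fold, Arg1 2.17-fold and Ass1 2.01-fold. These 4 genes belong to both lists, so the lists are not independent. In one-carbon and methionine metabolism 7 of 18 members rose (median 0.29; camera adjusted p = 1.46e-05; adjusted p = 0.644 with an estimated correlation), among them Bhmt, which remethylates homocysteine (2.04-fold, from 4402 ± 218 to 8982 ± 1067 CPM), Mat1a, which makes S-adenosylmethionine (2.46-fold), and Cth of cysteine synthesis (2.55-fold). The general hepatocyte list passed with 2 of 14 members rising, Hpx and Cps1 (camera adjusted p = 0.0166; adjusted p = 0.644 with an estimated correlation), and lost its call without HFD 334, HFD 335 or I3A 305 (adjusted p = 0.0545, 0.140 and 0.0595). Without HFD 335, 9 periportal, 5 one-carbon and 0 urea cycle genes rose, and those 3 lists still passed. Without I3A 305 the medians were 0.59 (periportal), 0.29 (urea cycle) and 0.15 (one-carbon), and the one-carbon median was 0.47 without I3A 303. Asl, Arg1 and Ass1 had log2 fold changes of 1.28, 1.12 and 1.01, and of 0.83, 0.61 and 0.55 without I3A 305. Leaving out HFD 334 left 1 one-carbon and 0 urea cycle genes rising.

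Cholesterol synthesis genes were higher, with positive fold changes in all 24 tested members, of which 6 rose (median 0.96; camera adjusted p = 2.19e-15; adjusted p = 0.644 with an estimated correlation). Mvk and Pmvk, successive kinases of the mevalonate pathway, rose 2.16-fold and 2.13-fold, and the later enzymes Lss and Hsd17b7 1.92-fold and 1.96-fold. Without HFD 335, 19 of the 24 rose (median 1.30), without I3A 305 10 and without I3A 303 0. Bile acid genes moved both ways: 4 of 18 members rose and 1 fell (median 0.11; camera adjusted p = 0.0111; adjusted p = 0.645 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis (chromosome 4, 6265612 to 6275633, minus strand), rose 3.70-fold from 77.1 ± 34.1 to 286 ± 50.3 CPM, and Cyp8b1 and Slco1a4 rose with it, whereas Abcb11, the export pump of bile salts, fell 1.45-fold. The bile acid list lost its call without HFD 335 (median 0.00864, adjusted p = 0.221; 3 rose and 3 fell) and without I3A 303 (adjusted p = 0.266), and its median was 0.22 without I3A 305.

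Respiratory chain transcripts, the subject of the series title, lay close to level between the groups. The 79 nuclear-encoded subunits of complexes I to V had a median log2 fold change of 0.032 (quartiles -0.045 to 0.11), and 72 of them lay within 0.2 of 0. Adjusted over the list alone 0 of the 79 passed in edgeR (smallest adjusted p 0.632). Their mean log2 CPM was 0.033 higher in I3A livers, beside a gap of 0.026 between the HFD livers and of 0.0060 between the I3A livers. Among the complexes, V differed most, with 15 of 17 members positive and 2 negative (median 0.10, camera adjusted p = 0.136). The mean log2 CPM of complex V was 0.115 higher in I3A livers, beside gaps of 0.0022 between the HFD livers and 0.0094 between the I3A livers. None of the 15 lists of mitochondrial function, from the 5 complexes to the mitochondrial ribosome, beta-oxidation and the TCA cycle, passed camera's threshold with all 4 libraries, while the TCA cycle list passed without I3A 303 (median 0.19, adjusted p = 0.0279). Single subunits measured 0.15 ± 0.16 for mt-Co1 (log2 fold change, SE), 0.17 ± 0.089 for Ndufs1 of complex I, -0.040 ± 0.10 for Sdha of complex II and -0.10 ± 0.10 for Cox4i1 of complex IV, none past the test. With single libraries left out mt-Co1 ranged from 0.082 to 0.24, Sdha from -0.095 to 0.029 and Cox4i1 from -0.17 to -0.015. The 13 proteins encoded in mitochondrial DNA had a median of 0.12 (camera adjusted p = 0.0941), and this list passed without I3A 305 (median 0.16, adjusted p = 0.0181), but its median was 0.073 without I3A 303 (adjusted p = 0.175) and 0.079 without HFD 334 (adjusted p = 0.356). Of 303 genes in the mitochondrial lists, 2 passed adjusted over the list alone: Ppargc1a, the coactivator known for driving mitochondrial biogenesis (chromosome 5, 51454250 to 51567726, minus strand), rose 2.09-fold from 7.97 ± 1.60 to 16.7 ± 0.298 CPM, and Twnk, the mitochondrial DNA helicase, fell 1.37-fold. Exons of Twnk overlap Mrpl43 on the opposite strand, and the kit is not stated to mark strand. In DESeq2, Ppargc1a passed (adjusted p = 0.0144) and Twnk did not (adjusted p = 0.242). DESeq2 called 0 genes in the lists of complexes I to V. It called mt-Nd6 (log2 fold change 0.40, adjusted p = 0.0467), 1 gene of peroxisomal beta-oxidation and 2 of the TCA cycle, all higher. The latter were Fh1 (0.76, adjusted p = 0.0129) and Dlst (0.44, adjusted p = 0.0276). Cpt1a, which admits fatty acids to mitochondria, measured 0.41 ± 0.12 without passing the test. In the list of biogenesis regulators that holds Ppargc1a and Twnk, 1 gene rose and 0 fell without HFD 334 or HFD 335, and 0 passed without I3A 303 or I3A 305. Without I3A 303, 1 gene of complex II and 1 of the TCA cycle rose and 2 of peroxisomal beta-oxidation fell.

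**Figure D4:**
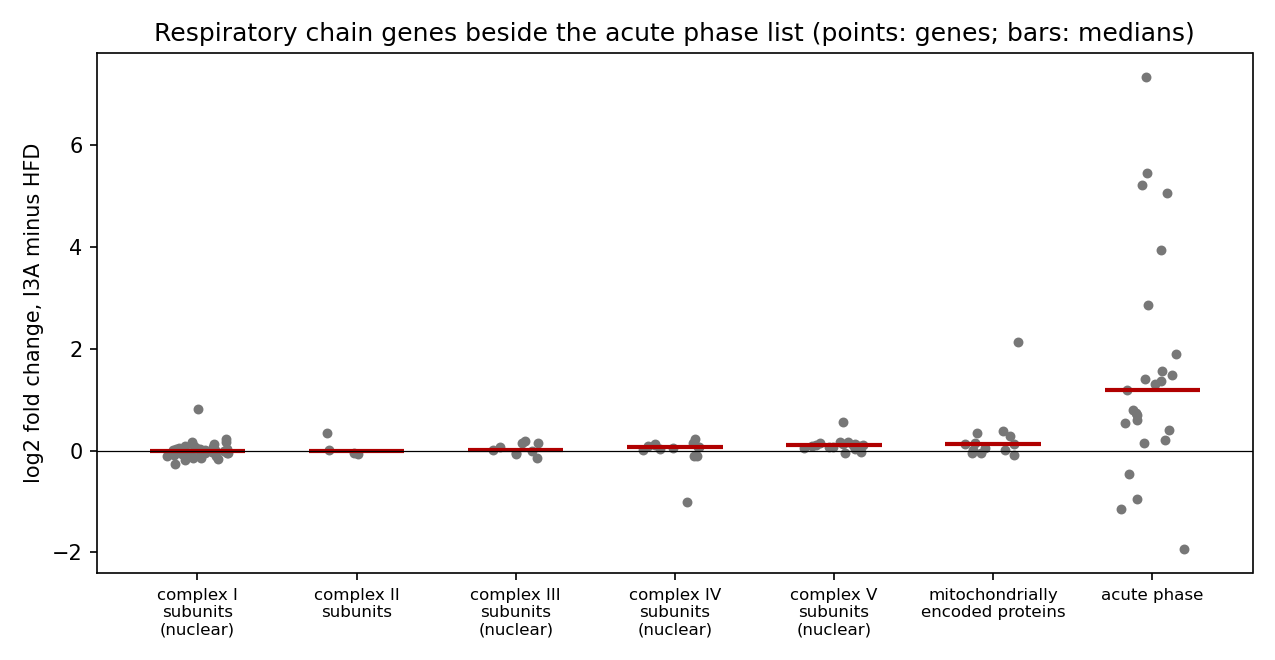
Log2 fold change (I3A minus HFD) of each tested gene in the lists of respiratory complexes I to V, of proteins encoded in mitochondrial DNA and, for scale, of the acute phase, with bars at the medians. The nuclear-encoded subunits have a median of 0.032, the acute phase genes 1.19.

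Lists of lipid handling mostly did not pass, but held members that did. Cd36, a fatty acid transporter, fell 2.50-fold (from 55.5 ± 14.3 to 22.2 ± 0.858 CPM) and the lipid droplet gene Plin4 1.84-fold within the list of steatosis genes linked to PPARgamma (2 of 7 fell; camera adjusted p = 0.0229; adjusted p = 0.644 with an estimated correlation). That list lost its call without HFD 335 (median -0.16, adjusted p = 0.364) or I3A 305 (adjusted p = 0.0920), and its median was -1.27 without I3A 303. In triglyceride synthesis, which did not pass (camera adjusted p = 0.0835), Dgat2, the enzyme of the last step, fell 1.44-fold and Fitm2 1.41-fold. The lipogenic genes Srebf1 (0.043 ± 0.29, SE), Fasn (-0.018 ± 0.19) and Scd1 (-0.19 ± 0.20) did not pass, and the sign of each depended on the library left out. The hepatokine Fgf21 measured -1.01 ± 0.64 and 0.37 without HFD 334, the library with its highest value of 82.1 CPM. Without HFD 335, Fgf21 measured -1.70 and Plin4 -0.51, against -0.88 with all libraries. Without HFD 334, 5 of the genes linked to PPARgamma fell and 1 rose, and without I3A 305 0 passed. In triglyceride synthesis 0 fell without HFD 335 or I3A 303 and 1 without I3A 305.

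Lists of sugar metabolism did not pass, but held members that did. Pfkfb3, an enzyme that sets the level of a glycolytic activator, fell 2.87-fold, while the glycolytic enzymes Tpi1 and Ldha rose 1.57-fold and 1.52-fold (list camera adjusted p = 0.0746). In gluconeogenesis and glycogen, 7 of 18 members rose and 2 fell (camera adjusted p = 0.120); the transaminases Got1 and Gpt2 rose 2.51-fold and 1.52-fold, and the glycogen enzymes Gbe1 and Pygl fell 1.85-fold and 1.70-fold. Among targets of the aryl hydrocarbon receptor, a sensor of many indoles, Cyp1a2 fell 1.74-fold (from 317 ± 11.4 to 182 ± 16.4 CPM) and Nqo1 rose 3.08-fold (list camera adjusted p = 0.841). Cyp1a1 stayed under 1 CPM in each library (-1.09 ± 0.55). Leaving out HFD 335 left 1 glycolytic gene rising and 3 falling, 2 of gluconeogenesis and glycogen rising and 5 falling, and 1 receptor target each way. Without HFD 334, 7 glycolytic genes fell and 1 rose and 2 receptor targets rose, without I3A 303 5 genes of gluconeogenesis and glycogen fell, without I3A 305 3 of them rose, and without either I3A library 0 receptor targets rose. The gluconeogenesis and glycogen list passed camera without HFD 334 (median 0.34, adjusted p = 0.0244) and without I3A 305 (median 0.23, adjusted p = 0.0159), and the glycolysis list without HFD 334 (median -0.068, adjusted p = 0.0292).

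Genes known to differ between male and female liver moved as lists. Female-biased genes were higher, with 4 of 7 rising (median 0.98; camera adjusted p = 3.12e-05; adjusted p = 0.644 with an estimated correlation): Cyp2c40 and Cyp2c69 rose 3.50-fold and 4.52-fold, Cyp4a14 1.97-fold and Cyp17a1 3.70-fold. Male-biased genes were lower, with 5 of 23 falling (median -0.25; camera adjusted p = 1.64e-04; adjusted p = 0.644 with an estimated correlation): Elovl3 fell 1.78-fold, Ugt2b1 1.60-fold, Hsd3b5 2.51-fold and Selenbp2 2.20-fold. Without HFD 335, 4 female-biased genes rose and 6 male-biased genes fell. The male-biased list lost its call without HFD 334 (median -0.19, adjusted p = 0.291). Only 7 of the 20 female-biased genes had enough counts to be tested, and the 3 of these that did not rise had negative fold changes. Cyp2c69 and Cyp4a14, like Cyp2c40, have close relatives that share sequence. Their values are uncertain to that extent, and their rises need not be independent. The sex of the animals is not in the labels. Without I3A 305, 3 male-biased genes fell and Cyp17a1 measured 0.77, against 2.52 without I3A 303, and Selenbp2 measured -0.74 without HFD 334, against -1.14 with all libraries.

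Interferon-stimulated genes were lower in I3A livers, with 6 of 30 falling (median -0.62; camera adjusted p = 3.95e-10; adjusted p = 0.645 with an estimated correlation). Bst2 fell 1.64-fold, Rtp4 2.29-fold (its exons overlap those of Gm45338 on the same strand, 253 against 1209 counts), Irgm1 1.52-fold and Ifi27 1.40-fold. Without HFD 335, 2 fell (median -0.48), and without I3A 305 the median was -0.38. Markers of sinusoidal endothelial cells were lower as a list, with negative fold changes in all 17 members and 0 past the test singly (median -1.19; camera adjusted p = 7.20e-10; adjusted p = 0.685 with an estimated correlation). Pecam1 measured 20.6 ± 10.9 CPM in HFD and 8.29 ± 3.10 CPM in I3A livers and Fcgr2b 47.8 ± 8.55 CPM in HFD and 18.1 ± 11.6 CPM in I3A livers (SD, n = 2). The log2 fold change of Pecam1 was -1.32, and -0.64 without HFD 335, and that of Fcgr2b -1.41, with -2.26 without I3A 303 and -0.87 without I3A 305. The endothelial median was -0.60 without I3A 305, -0.82 without HFD 335 and -2.13 without I3A 303, and between HFD 334 and I3A 303 alone it was -0.24. The interferon median between HFD 334 and I3A 303 alone was -0.18. The number of interferon-stimulated genes that fell was 17 without I3A 303, 0 without I3A 305 and 2 without HFD 334, and 14 endothelial markers fell without I3A 303 and 12 without HFD 334.

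Lists of stromal and lymphoid cells were lower, and each lost its call without library HFD 335, which held the muscle transcripts. These were hepatic stellate cells (median -0.80; camera adjusted p = 2.09e-04; adjusted p = 0.693 with an estimated correlation), fibrosis and matrix (-1.01; camera adjusted p = 6.76e-04; adjusted p = 0.735 with an estimated correlation), smooth muscle and mesothelium (-2.64; camera adjusted p = 0.0111; adjusted p = 0.693 with an estimated correlation), B and plasma cells (-1.80; camera adjusted p = 0.00828; adjusted p = 0.685 with an estimated correlation), T and NK cells (-0.40; camera adjusted p = 0.0111; adjusted p = 0.685 with an estimated correlation) and MHC class II (-0.76; camera adjusted p = 0.0111; adjusted p = 0.696 with an estimated correlation). No member of these 6 lists passed adjusted over its list alone, but without HFD 334, which leaves HFD 335 as the control, 17 matrix, 7 smooth muscle, 3 stellate, 4 B and plasma cell and 4 MHC class II genes fell, and without I3A 303 10 stellate genes fell. Without HFD 335 none of the 6 passed, with medians of -0.46, -0.047, -0.20, 0.29, -0.63 and -0.18 in the same order. Without I3A 305 the calls of stellate cells (adjusted p = 0.243), T and NK cells (0.105) and MHC class II (0.128) were lost, and without I3A 303 that of smooth muscle (0.0614). Over the 4 fits that each left out 1 library, medians ranged from -1.89 to -0.11 for stellate cells, -1.29 to -0.40 for T and NK cells, -1.19 to -0.18 for MHC class II, -1.72 to -0.047 for matrix genes, -1.74 to 0.29 for B and plasma cells and -3.55 to -0.20 for smooth muscle. Between HFD 334 and I3A 303 alone the medians were 0.17 (stellate cells), 0.32 (matrix genes), 0.057 (smooth muscle) and 0.030 (B and plasma cells). Those of T and NK cells and MHC class II were -0.26 and -0.050. Col1a1, the main fibrillar collagen, had 2.02 and 13.1 CPM in the HFD libraries and 4.12 and 2.50 CPM in the I3A libraries.

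Of the remaining called lists, cytosolic ribosomal proteins were higher by a small amount, with positive fold changes in 69 of 79 members and 0 past the test singly (median 0.091; camera adjusted p = 6.76e-04; adjusted p = 0.685 with an estimated correlation). Rpl3 measured 0.46 ± 0.091 (log2 fold change, SE), and the list median was 0.14 without HFD 335 and 0.14 without I3A 303. Circadian clock genes were lower as a list (median -0.39; camera adjusted p = 0.00807; adjusted p = 0.685 with an estimated correlation) with 0 of 20 past the test singly. Fold changes were negative in 16 members and positive in 4. Arntl, a core activator of the clock and 1 of these 4, measured 1.06 ± 0.39 (0.41 without I3A 305). The deubiquitinase gene Usp2 measured -0.92 ± 0.26. The list mixes genes of opposed arms of the clock, compared in the closing paragraph, so a lower list does not by itself mean a lower clock. The clock list lost its call without HFD 334 (median -0.23) and without I3A 305 (median -0.16, adjusted p = 0.103). Without I3A 303, 9 clock genes fell and 1 rose.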

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

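The robust fit, list medians between HFD 334 and I3A 303 and the second reading of lists without HFD 335 were chosen after seeing the data; the other alternatives were planned, leaving out each library among them. The count of 0 changed genes became 619 without a filter on low counts (232 higher, 387 lower; 502 of them tested with the filter), 325 with DESeq2 (175 higher, 150 lower) and between 0 and 343 with single libraries left out. All 311 DESeq2 calls that edgeR also tested had an unadjusted edgeR p under 0.05 in the same direction. It stayed 0 under RLE, upper-quartile and library size scaling, the stricter filter, limma-voom, the robust fit (smallest adjusted p 0.0977), protein-coding genes alone and both other thresholds. The cause of the differences was not tested. With 1 library left in a group, that library is assumed to vary like the other group.

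The 25 list calls became 0 with an estimated correlation and 0 by fry, 15 to 29 with single libraries left out, 24 to 33 under the other scalings and filters. Camera's direction turned for 1 called list, fibrosis and matrix, which was up without HFD 335. Its median ranged from -1.72 to -0.047 with single libraries left out. Medians turned positive between HFD 334 and I3A 303 for fibrosis and matrix (0.32), stellate cells (0.17), smooth muscle and mesothelium (0.057) and B and plasma cells (0.030). The median of B and plasma cells was also positive without HFD 335 (0.29). The 20 leading genes kept their direction in all 260 comparisons with an alternative and passed the threshold in 64 of these. The kept direction adds little, since the 20 were picked for groups that did not overlap and for small p in these same libraries. Of 258 genes in the tables, 23 changed sign under some alternative. Scaling by library size moved the median of all genes by -0.090. Depth limited genes such as Tnf, with 1 to 5 counts per library.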

Other observations

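Car3, an abundant carbonic anhydrase of hepatocytes and adipocytes, was 7.03-fold lower in I3A livers (1067 ± 222 CPM in HFD and 152 ± 103 CPM in I3A livers; SD, n = 2) and passed edgeR adjusted over the adipocyte list alone (adjusted p = 0.00909), whose other members did not, though without HFD 334 6 fell and 1 rose. The log2 fold change of Car3 was -3.74 without I3A 303 and -2.25 without I3A 305. Chemokine genes went both ways without passing: Cxcl14 measured 3.58 ± 0.92 (log2 fold change, SE) and the interferon-induced Cxcl10 -1.88 ± 0.46, with Cxcl14 at 1.92 without I3A 305. Exons of Cxcl10 (168 counts over the 4 libraries) overlap those of Art3 (155 counts) on the opposite strand. Kupffer cell markers, of the resident liver macrophage, had a median of 0.21 with Cd163 at 0.94 ± 0.30 and Clec4f at 0.38 ± 0.13 (camera adjusted p = 0.0689), and passed without I3A 305 (median 0.25, adjusted p = 0.0265), but their median was 0.10 without HFD 334 (adjusted p = 0.120). Cd163 measured 0.61 without HFD 334 and Clec4f 0.25 without HFD 335. Among targets of the receptors CAR and PXR, Cyp3a13 and Cyp2c38 rose 2.47-fold and 1.69-fold over the list alone, while Cyp3a11 measured -1.13 ± 0.37 and did not pass. Without I3A 305, Cyp3a13 measured 0.83, against 1.31 with all libraries, and Cyp3a11 -0.68; without I3A 303, Cyp3a11 measured -1.78. The number of CAR and PXR targets that rose was 0 without HFD 335 and 1 without I3A 303 or I3A 305, and without HFD 334, 3 rose and 3 fell. In the list of insulin and AMPK signalling Foxo3 fell 1.43-fold and Igfbp1 rose, while without HFD 335 2 members rose and 4 fell and without either I3A library 0 fell. Genes of tryptophan and indole metabolism held 0 of 18 members past the test, with Kynu of the kynurenine pathway at 0.48 ± 0.11 (camera adjusted p = 0.814); without I3A 303, 4 members rose and 1 fell.

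The other lists not yet described did not pass camera's threshold with all 4 libraries: pericentral hepatocyte (median -0.24, camera adjusted p = 0.105), neutrophil (median 0.48, camera adjusted p = 0.141), intestine (median 0.11, camera adjusted p = 0.203), monocyte-derived and lipid-associated macrophage (median -0.45, camera adjusted p = 0.262), erythroid cell (median -0.49, camera adjusted p = 0.274), cholangiocyte (median -0.053, camera adjusted p = 0.771), adipocyte (median 0.31, camera adjusted p = 0.771), NRF2 targets (median 0.025, camera adjusted p = 0.393), PPARalpha targets (median -0.084, camera adjusted p = 0.896), apoptosis and p53 targets (median -0.11, camera adjusted p = 0.424), cell cycle (median -0.11, camera adjusted p = 0.814), inflammatory cytokines and chemokines (median -0.15, camera adjusted p = 0.771), fatty acid synthesis (median 0.013, camera adjusted p = 0.883), fatty acid uptake and binding (median -0.084, camera adjusted p = 0.203), lipoprotein and cholesterol transport (median -0.042, camera adjusted p = 0.986) and insulin and AMPK signalling (median 0.029, camera adjusted p = 0.986). Some passed with 1 library left out: without HFD 334 those of adipocytes (median -2.86, adjusted p = 2.29e-14), monocyte-derived macrophages (median -0.97, adjusted p = 1.28e-04), erythroid cells (median -1.18, adjusted p = 0.00131) and fatty acid uptake (median -0.048, adjusted p = 0.00996), without I3A 303 PPARalpha targets (median -0.20, adjusted p = 0.0197) and without I3A 305 intestine (median 0.49, adjusted p = 0.0181). Without HFD 335 the medians of monocyte-derived macrophages (0.22), erythroid cells (0.30) and cholangiocytes (0.40) turned positive, and the adipocyte median was -3.74 without I3A 303 and -2.25 without I3A 305. Over the list alone, Cyp4a32 and Cyp4a14 rose among PPARalpha targets, Wfdc21 rose in the neutrophil list, Cyp1a2 fell in the pericentral list, and in fatty acid uptake Acsl4 rose and Cd36 fell, while the other lists of this paragraph held 0 such members besides Car3, Foxo3 and Igfbp1. Without HFD 334 there rose and fell, in this order, 1 and 1 of PPARalpha targets, 0 and 0 of the pericentral list, 0 and 0 of neutrophils, 0 and 5 of monocyte-derived macrophages, 0 and 5 of erythroid cells and 1 and 4 of fatty acid uptake. Without HFD 335 there rose and fell, in this order, 3 and 1 of PPARalpha targets, 2 and 2 of the pericentral list, 0 and 0 of neutrophils, 0 and 1 of erythroid cells, 1 and 0 of intestine, 2 and 1 of NRF2 targets, 0 and 2 of apoptosis genes, 0 and 1 of cell cycle genes, 1 and 2 of lipoprotein transport, 3 and 3 of fatty acid synthesis and 2 and 1 of fatty acid uptake. Without I3A 303 there rose and fell, in this order, 3 and 7 of PPARalpha targets, 1 and 2 of the pericentral list, 1 and 0 of intestine, 1 and 0 of cytokines, 2 and 1 of lipoprotein transport, 1 and 2 of fatty acid synthesis and 1 and 3 of fatty acid uptake. Without I3A 305 there rose and fell, in this order, 0 and 0 of fatty acid uptake. In 9 of the 63 tested lists, none of them called, the median and camera's direction differed in sign.

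The tests in the paragraphs that follow were all chosen after the results were seen. The higher acute phase list could come from reads shared between copies of the Saa, Orm and Serpina3 families, or from white blood cells, which make Lcn2 too. The 16 members outside those families had a median log2 fold change of 0.65 (quartiles 0.19 to 1.32), with mean log2 CPM of 9.11 and 9.67 in I3A against 8.53 and 8.67 in HFD livers, which argues against shared reads as the whole cause. S100a8 and S100a9, abundant in neutrophils, were higher by 0.534 CPM together. That is a share of 0.0023 of the difference of 235 CPM in Lcn2 (both by library totals), which argues against neutrophils as the source of Lcn2. The 13 genes of the neutrophil list summed to 421 and 447 CPM in I3A against 325 and 337 CPM in HFD livers. Only 3 of them had enough counts to be tested. Wfdc21 rose (0.48 ± 0.11), S100a9 had at most 1.26 CPM in any library and Csf3r measured -0.0061 ± 0.45. The sum therefore does not show that neutrophil markers rose together. An unlabelled difference in cage, day or health of the animals cannot be told apart from I3A, since 0 labels give a batch, cage or date; an effect of I3A itself stays open as well.

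Lower cell type lists may come from muscle, connective or other tissue carried into library HFD 335; of the 5 called cell type lists that were lower, 1 still passed without that library, the sinusoidal endothelial list (median -0.82). The smooth muscle and mesothelium list stood apart in HFD 335 alone, as carried-over tissue would give. HFD 334 lay above the I3A mean by a share of 0.043 of the gap of HFD 335 (mean log2 CPM). The list summed to 7.73 CPM in HFD 334, 118 CPM in HFD 335 and 7.03 and 6.41 CPM in the I3A livers. These sums had already marked HFD 335 out, so they describe the pattern and add no separate support. B and plasma cells also stood apart in HFD 335 alone (share 0.031). Their list without Xbp1, which hepatocytes also express, summed to 16.6 CPM in HFD 334, 172 CPM in HFD 335 and 13.6 and 21.5 CPM in the I3A livers. These values cannot tell carried-over tissue from a difference in that liver itself. For sinusoidal endothelial cells (share 0.55), T and NK cells (0.63; median -0.63 without HFD 335) and stellate cells (0.38; median -0.46) carried-over tissue cannot be told apart from an effect of I3A, since the I3A livers lay 1.28, 0.62 and 1.60 apart (log2), more than HFD 334 stood above their mean.

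The lower heat shock list was still called without HFD 335 (median -0.53; mean log2 CPM 5.83 in HFD 334 against 5.24 and 5.18 in I3A livers), which argues against carried-over tissue as the whole cause. A lower temperature of the tissue is a candidate explanation: Cirbp, which is known to rise in the cold, had a log2 fold change of 1.05 (16.2 and 9.89 CPM in HFD, 26.2 and 27.6 CPM in I3A livers), and Rbm3, known for the same, measured 1.44 ± 0.19 (SE). Time of day at collection cannot be told apart from this. The arm of the clock with Arntl, Npas2 and Clock stood higher against the arm with Dbp, Per2, Per3, Nr1d1 and Nr1d2 by 0.68 in I3A 303 and 2.11 in I3A 305, relative to the HFD mean around which HFD livers lay at -0.22 and 0.22, and the unequal size in the I3A livers keeps it open. No label gives the hour or the temperature. A difference in hour would concern whole libraries, so for the other genes and lists it cannot be told apart from I3A either.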
